A study of Mus musculus with 19 samples.

How the data were processed

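RNA of 19 mouse livers and liver tumours was sequenced from poly(A)-selected, strand-specific libraries. The deposited table gives a whole-number count per gene and library for 55421 genes, of which 24684 had no count in any library. Per the labels, the submitters' processing notes list STAR 2.6.1a, RSEM, bedtools 2.27.1 and DESeq2 1.22.2 with build GRCm38, but the role of each tool, the order of the steps and the annotation release are not given in the sources used here. The deposited counts showed no sign of normalisation and were used as they are. As RSEM is among the listed tools, they may be its expected counts rounded to whole numbers, and the floors and counting intervals would then rest on estimated counts. Gene identifiers were matched to GENCODE M21, which holds 54587 of them with the same version and 55154 when versions are ignored, and coordinates come from it. The depth per library, taken as the total count, limits the precision of low values, and intervals and floors cover counting error only.

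Groups were mutants and controls at 2 months, and controls, tumour-free mutant tissue and tumours at 9 months. The 2 tumours of mutant 1 were summed, so that the 19 libraries stand for 15 animals. The 7 comparisons, the groups, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for the alternatives named as later choices in the closing section. Each comparison was fitted on its own groups with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's expression filter, libraries were scaled by TMM, dispersions were estimated robustly and the quasi-likelihood test was applied, with Benjamini-Hochberg adjusted p under 0.05 as the threshold over all genes tested. Standard errors are those of the fitted log2 change. Levels are CPM after TMM scaling. A fold against a group with no count is given as at least the ratio to a floor of 3 counts over the group, and a group with 1 to 3 counts has its ratio with a 95% counting interval.

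Gene lists were written from general knowledge of liver biology, 57 in all, of which 56 were tested and 1 served to check the sex of the animals. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The rotation test fry asked whether a list moves on balance one way, without comparing it with other genes. Adjusted p-values of lists cover all lists tested in a comparison. With the estimated correlation no list passed in the first 5 comparisons, 1 did in the tumour-free change with time and 2 did in the tumour change with time.

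The genes named follow a rule. Jun, Fosl2 and Myc are given in every comparison. Protein coding genes with the largest rises and falls are named where the adjusted p was under 0.05, the mean reached 5 CPM in the higher group and, outside the tests of change with time, every library of one group lay beyond every library of the other. The other names are the list members with the smallest adjusted p, up to 4 in a list that passed and up to 2 in one that did not. A list of at most 12 tested members may be given in full, and a gene named in one comparison may be given in others. Some genes that the rule names are not reported here. Genes outside the rule appear only under the other observations.

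The alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library size alone, no expression filter, 1 fit over all 5 groups, a 2-fold minimum, protein coding genes only, the animal or replicate number as a block, tumours as separate libraries, and leaving out each library in turn. Pairing by number was checked on the correlation, across genes, of the libraries' deviations from their group means. Tumours and tumour-free tissue of the same animal gave r from 0.00449 to 0.293 and of different animals from -0.222 to 0.0849, and the animal as a block was run as an alternative for that comparison. Both the gene test and the list test were tested on simulated data with known changes. For a 4-fold change the gene test found 95.5% of changed genes at 2 months and 87.9% in tumour-free tissue. It found 50.0% in tumours against controls and 68.2% in tumours against tumour-free tissue. At most 9 unchanged genes passed in any comparison with edgeR. Unchanged genes were 6 of 119 calls at 2 months, 9 of 95 in tumour-free tissue and 6 of 40 in tumours against controls. They were 4 of 50 in tumours against tumour-free tissue and 9 of 124 between the controls. For the changes with time they were 6 of 65 in tumour-free tissue and 1 of 53 in tumours. These shares lay above the one the adjusted threshold is meant to hold, except near it at 2 months and below it in the last. On the same data at most 11 passed with limma voom and at most 54 with DESeq2, the latter among 123 genes called in tumours against tumour-free tissue. Isoforms, and reads that would tell the transgene from the animal's own genes, were not analysed here.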

Results

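Liver RNA was sequenced from adult male C57BL/6 mice that carry a transgene for a dimer of the AP-1 proteins c-Jun and Fra-2, and from control littermates. AP-1 is a family of transcription factors that bind DNA as pairs. Doxycycline keeps the transgene silent, and it was withdrawn at 3 weeks of age in mutants and controls alike. Livers were collected 2 months after the withdrawal (3 mutants and 6 controls) or 9 months after it (3 mutants and 3 controls). At 9 months each mutant gave 1 sample of liver without visible tumour, called tumour-free here, and visible tumours: mutant 1 gave 2 and mutants 2 and 3 gave 1 each. The 19 libraries come from 15 animals, and the 2 tumours of mutant 1 were added together, so that every n below counts animals. The total count per library, in M (mega) counts, ran from 14.3 to 17.4 M in the 2-month controls, from 15.7 to 18.8 M in the 2-month mutants, from 19.9 to 20.9 M in the 9-month controls, from 18.98 to 22.1 M in tumour-free tissue and from 19.5 to 21.6 M in tumours. Each time point was sequenced in a run of its own, so time and run cannot be told apart. Levels are TMM-normalised counts-per-million (CPM) as mean ± SD, log2 changes carry their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction.

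At 2 months, mutants against controls (n = 3 and 6) show which transcripts differ with the transgene at the earlier time. Fosl2, the gene of Fra-2, rose from 12.5 ± 3.7 to 781 ± 127 CPM (log2 change 5.97 ± 0.225, adjusted p = 1.43e-08). Jun, the gene of c-Jun, rose from 17.2 ± 5.79 to 619.8 ± 77.7 CPM (5.18 ± 0.256, adjusted p = 1.14e-07). These counts do not separate the animal's own transcripts from those of the transgene. Myc was at 7.61 ± 3.45 CPM in controls and 9.50 ± 4.49 CPM in mutants (0.34 ± 0.403, adjusted p = 0.533), and its direction turned without mutant 3 (-0.11, adjusted p = 0.884, range over the alternatives 0.0536 to 0.884). Fosl2 (ENSMUSG00000029135.10) spans positions 32135801 to 32157842 of chromosome 5 in build GRCm38, Jun (ENSMUSG00000052684.4) positions 95049034 to 95052222 of chromosome 4, and Myc (ENSMUSG00000022346.15) positions 61985391 to 61990374 of chromosome 15. Of 9 tested members of the AP-1 family, 4 rose and none fell, by either adjustment (list adjusted p = 0.018, adjusted p = 0.566 with an estimated correlation). Jun and Fosl2 are among the 4, and their counts may include the transgene, so the list test is not separate from their rise.

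**Figure D1:**
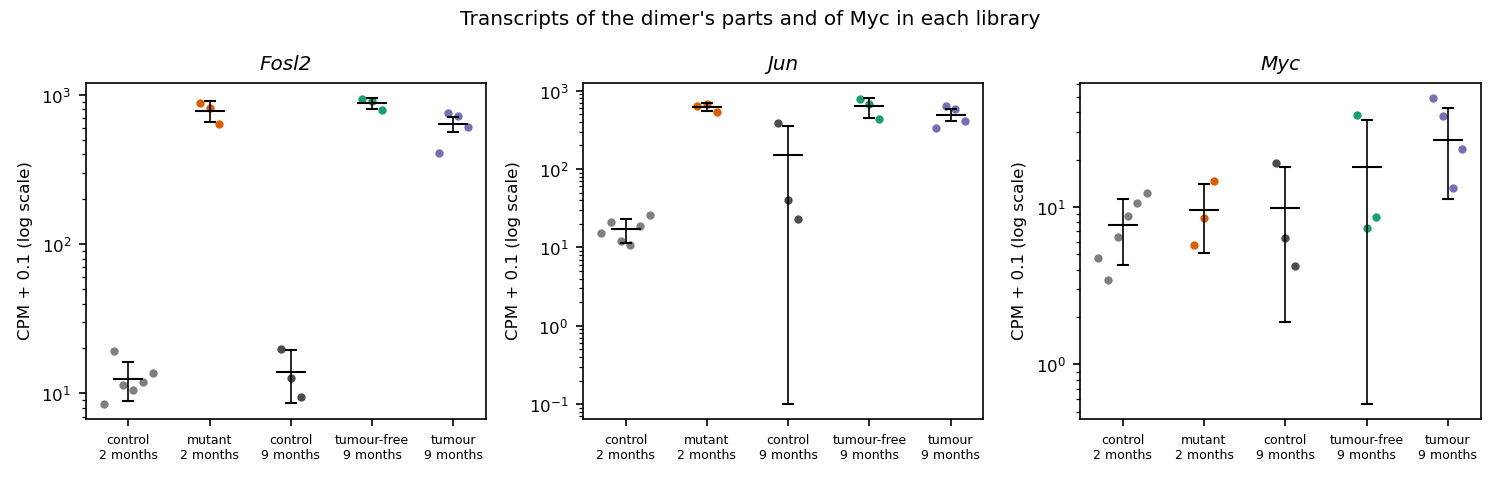
Level of Fosl2, Jun and Myc in each library, as CPM plus 0.1 on a log axis, by group, with 1 point per library (tumours 1a and 1b separately) and black bars for the mean and SD over animals. Fosl2 lay between 8.38 and 19.9 CPM in all controls, and Jun reached 387 CPM in 9-month control 1.

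Hepatocyte products and metabolic enzymes fell in the 2-month mutants. Fabp1, the fatty acid binding protein of hepatocytes, fell from 5392 ± 874 to 10.9 ± 3.45 CPM (log2 change -8.95 ± 0.319). Of 33 tested genes of fatty acid oxidation and ketogenesis, 27 fell and 3 rose, the same number falling and 4 rising when adjusted over the list alone (list adjusted p = 2.42e-08, adjusted p = 0.527 with an estimated correlation). Acaa1b and Ehhadh, enzymes of the peroxisome, changed by -3.71 ± 0.185 and -1.32 ± 0.108. Of 36 nuclear genes of oxidative phosphorylation, 33 fell and none rose, or 34 when adjusted over the list alone (list adjusted p = 5.65e-10, adjusted p = 0.574 with an estimated correlation). Their steps were small, as in Cyc1 (-0.73 ± 0.113) and Uqcrc2 (-0.63 ± 0.0966), both of complex III. Among 30 cytochrome P450 and other phase I enzymes, which oxidise drugs and steroids, 21 fell and 4 rose, or 22 and 7 when adjusted over the list alone (list adjusted p = 0.000127, adjusted p = 0.566 with an estimated correlation). Cyp2a5 changed by -8.06 ± 0.645 and Cyp2c37 by -3.83 ± 0.38, while Cyp4v3 rose by 1.53 ± 0.138. Amino acid catabolism lost transcript in 18 of 30 genes and gained it in 2, or in 18 and 3 when adjusted over the list alone (list adjusted p = 0.000565, adjusted p = 0.616 with an estimated correlation). Hao1, a peroxisomal oxidase, was among the largest falls of all (-9.09 ± 0.159, from 378.6 ± 33.7 to 0.683 ± 0.0316 CPM).

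Secreted proteins and male-biased genes fell with them. Alb, the gene of albumin, fell from 101400 ± 7560 to 30740 ± 4830 CPM (log2 change -1.72 ± 0.139, adjusted p = 3.11e-06). Its share of all counts was 3.25% ± 0.345 in mutants and 8.89% ± 0.675 in controls (exact two-sided permutation test over 84 splits, p = 0.0119). Of 30 tested secreted hepatocyte proteins, 21 fell and 3 rose, or 22 and 3 when adjusted over the list alone (list adjusted p = 2.61e-05, adjusted p = 0.566 with an estimated correlation). Apoa1, the main protein of high density lipoprotein, changed by -2.25 ± 0.18, and Apob, that of low density lipoprotein, rose by 1.11 ± 0.112. Of 20 genes with male-biased expression in mouse liver, 12 fell and 2 rose, by either adjustment (list adjusted p = 3.53e-05, adjusted p = 0.566 with an estimated correlation). Of 16 female-biased genes 6 rose and 5 fell, by either adjustment, and the list did not pass (list adjusted p = 0.748). Elovl3, a fatty acid elongase of the male-biased list, went from 381.2 ± 237 to 0.372 ± 0.0451 CPM, Hsd3b5, a steroid dehydrogenase, from 258.2 ± 119 to 0.261 ± 0.135 CPM, and Slco1a1, an organic anion carrier, from 561.5 ± 86.8 to 0.908 ± 0.101 CPM. Bile acid synthesis and transport had 13 lower and 2 higher genes of 23, or 14 and 2 when adjusted over the list alone (list adjusted p = 0.00246, adjusted p = 0.527 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase that sets the share of cholic acid, changed by -7.04 ± 0.553. The 2 that rose were transporters, Abcb4 (2.02 ± 0.111) and Slc51b (6.16 ± 0.271).

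Cell division, matrix and epithelial transcripts rose in the same 2-month mutants. Of 29 tested genes of mitosis, 23 rose and none fell, or 25 when adjusted over the list alone (list adjusted p = 3.16e-06, adjusted p = 0.566 with an estimated correlation). Their levels stayed low, as in Tpx2, a spindle protein, which rose from 0.575 ± 0.109 to 2.25 ± 0.923 CPM (log2 change 1.98 ± 0.301), and in the kinase Aurka (1.76 ± 0.285). Of 22 myofibroblast and matrix genes, 19 rose and none fell, or 20 when adjusted over the list alone (list adjusted p = 0.000129, adjusted p = 0.616 with an estimated correlation), among them the collagen cross-linking enzyme Loxl2 (1.98 ± 0.23) and the proteoglycan Dcn (0.68 ± 0.132). Extracellular proteases and invasion genes rose in 12 of 16 and fell in 1, or 14 and 1 when adjusted over the list alone (list adjusted p = 0.000565, adjusted p = 0.566 with an estimated correlation). Itga6, a laminin receptor, rose by 3.08 ± 0.195. Of 18 targets of the growth regulators YAP and TEAD, 11 rose and none fell, or 13 when adjusted over the list alone (list adjusted p = 0.000565, adjusted p = 0.527 with an estimated correlation). Tgfb2, a growth factor, rose by 3.82 ± 0.272 and Crim1 by 1.92 ± 0.109. Of 15 markers of bile duct cells and progenitors 8 rose and none fell, by either adjustment (list adjusted p = 0.0055, adjusted p = 0.616 with an estimated correlation), with St14, an epithelial membrane protease, at 6.25 ± 0.249. Markers of monocyte-derived and lipid-associated macrophages rose in 8 of 11, by either adjustment (list adjusted p = 0.00724, adjusted p = 0.566 with an estimated correlation), with Gpnmb at 8.40 ± 0.455 and the lectin Lgals3 at 4.22 ± 0.197. Of 23 targets of p53, 15 rose and 6 fell, by either adjustment (list adjusted p = 0.0125, adjusted p = 0.527 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 3.08 ± 0.42, and Phlda3 by 2.75 ± 0.29.

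Among the largest rises at 2 months were transcripts that control liver nearly lacked. Tcam1, a cell adhesion gene, went from 0.107 ± 0.0965 to 86.7 ± 16 CPM, Meltf, an iron-binding membrane protein, from 0.152 ± 0.156 to 92.8 ± 51.6 CPM, and Sult1e1, the estrogen sulfotransferase, from 0.186 ± 0.175 to 134.6 ± 29 CPM. Add2, a membrane skeleton protein, had no count in any of the 6 controls and was at least 184-fold higher in mutants. In all, 5883 of 13773 tested genes changed at 2 months, 3067 higher and 2816 lower, and 2352 of them changed at least 2-fold. With the replicate number as a block 3290 passed. Scaled by library size alone, the median of all genes was 0.286 on the log2 scale, against 0.0105 with TMM, and the split became 5445 higher and 1562 lower. That scaling also ended the list calls of the AP-1 family (adjusted p = 0.0875), p53 targets (0.075), bile duct cell markers (0.0616) and monocyte-derived macrophage markers (0.058). It left 22 lower and 5 higher genes of fatty acid oxidation, 19 and 7 phase I enzymes, 13 and 6 of amino acid catabolism, 13 and 4 of bile acids, and 3 lower and 15 higher p53 targets.

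At 9 months, tumour-free mutant tissue against controls (n = 3 and 3) shows the same contrast later in life, in liver without visible tumour. Fosl2 rose from 13.9 ± 5.38 to 877 ± 78.4 CPM (log2 change 5.97 ± 0.315, adjusted p = 9.85e-06). Jun was at 150.2 ± 206 CPM in controls and 631.8 ± 178 CPM in mutants and did not pass (2.08 ± 1.1, adjusted p = 0.204). Control 1 alone carried 387 CPM of Jun, and without it Jun passed (4.30, adjusted p = 0.000247, range over the alternatives 0.000247 to 0.41). Myc was at 9.81 ± 8.06 and 18.0 ± 17.5 CPM (0.87 ± 0.862, adjusted p = 0.482), and its direction turned without tumour-free sample 1 (-0.31, adjusted p = 0.745, range over the alternatives 0.026 to 0.745). In each 9-month group the animal numbered 1 also had the highest level of 23 of 25 immediate early and heat shock genes, which respond within minutes to stress and growth signals. Among the largest rises were Muc13, a mucin of gut epithelium, from 0.702 ± 0.384 to 226.6 ± 63.5 CPM, Mep1a, a protease of the intestinal brush border, from 0.133 ± 0.142 to 67.4 ± 23.6 CPM, and Tcam1, from 0.341 ± 0.111 to 107.5 ± 28.8 CPM. Among the largest falls were the urinary proteins Mup14, with no count in tumour-free tissue and at least 287-fold lower, and Mup17 (-9.25 ± 0.895), and Cyp4a14 (-9.46 ± 0.463), Slco1a1 (-9.53 ± 0.805) and the lipid droplet protein Cidea (-9.72 ± 1.26).

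Lipid and energy metabolism fell in 9-month tumour-free tissue. Of 33 tested genes of fatty acid oxidation and ketogenesis, 29 fell and 1 rose, or 30 and 2 when adjusted over the list alone (list adjusted p = 1.6e-11, adjusted p = 0.478 with an estimated correlation). Fabp1 went from 7000 ± 2010 to 21.1 ± 5.43 CPM, and Cyp4a10, a fatty acid hydroxylase, from 429.3 ± 152 to 6.28 ± 2.67 CPM. All 30 changed genes among 36 of oxidative phosphorylation fell, or 33 when adjusted over the list alone (list adjusted p = 1.22e-08, adjusted p = 0.478 with an estimated correlation), with Ndufs3 at -0.75 ± 0.11. Fatty acid and triglyceride synthesis fell in 13 of 22 genes and rose in none, or fell in 15 when adjusted over the list alone (list adjusted p = 1.97e-05, adjusted p = 0.478 with an estimated correlation). Me1, the malic enzyme, changed by -3.89 ± 0.196, and the desaturase Fads2 by -2.13 ± 0.156. Of 11 lipid droplet genes 8 fell and none rose, or 9 when adjusted over the list alone (list adjusted p = 0.000223, adjusted p = 0.478 with an estimated correlation). Plin2, a coat protein of droplets, went from 799.3 ± 118 to 136.8 ± 6.16 CPM, Plin4 from 53.8 ± 13.6 to 3.18 ± 0.343 CPM, and Fitm1 changed by -4.45 ± 0.296. Of 30 phase I enzymes, 17 fell and 3 rose, or 21 and 3 when adjusted over the list alone (list adjusted p = 2.22e-06, adjusted p = 0.478 with an estimated correlation), with Cyp2c54 at -4.78 ± 0.284.

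Tumour, stromal and macrophage markers rose in 9-month tumour-free tissue. Of 19 oncofetal and liver tumour markers, 13 rose and none fell, by either adjustment (list adjusted p = 4.72e-06, adjusted p = 0.478 with an estimated correlation). Vil1, villin of the brush border, rose from 0.952 ± 0.284 to 210 ± 44.3 CPM, the desaturase Scd2 by 3.86 ± 0.232 and Igf2bp2, an RNA-binding protein of fetal liver, by 2.73 ± 0.195. Of 38 genes of mitosis 10 rose and none fell, and only 2 rose when adjusted over the list alone (list adjusted p = 6.72e-05, adjusted p = 0.534 with an estimated correlation). Hmmr changed from 0.342 ± 0.206 to 2.04 ± 0.909 CPM and Top2a, a topoisomerase of dividing cells, from 1.69 ± 1.09 to 5.98 ± 0.805 CPM. Proteases and invasion genes had 13 higher and 1 lower of 18, by either adjustment (list adjusted p = 0.000223, adjusted p = 0.478 with an estimated correlation). The matrix protease Mmp14 rose by 1.99 ± 0.162, whereas the laminin chain Lamb3 was the one that fell (-2.63 ± 0.186). Matrix genes rose in 13 of 23 and fell in none, or rose in 15 when adjusted over the list alone (list adjusted p = 0.000223, adjusted p = 0.499 with an estimated correlation), with the fibrillin Fbn1 at 1.69 ± 0.213 and the proteoglycan Lum at 1.83 ± 0.257. Of 14 markers of Kupffer cells and macrophages, 11 rose and none fell, by either adjustment (list adjusted p = 0.000731, adjusted p = 0.478 with an estimated correlation). Cd68, a lysosomal protein, rose by 2.46 ± 0.197 and Csf1r, the receptor that macrophages need to survive, by 1.12 ± 0.132.

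Amino acid stress and epithelial genes rose as well. Of 19 genes of the amino acid stress response under ATF4, 10 rose and 1 fell, by either adjustment (list adjusted p = 0.0018, adjusted p = 0.478 with an estimated correlation). Asns, asparagine synthetase, rose by 7.33 ± 0.335 to 102.4 ± 24.5 CPM. Bile duct and progenitor markers rose in 8 of 16 and fell in none, or rose in 9 when adjusted over the list alone (list adjusted p = 0.00207, adjusted p = 0.478 with an estimated correlation). St14 rose by 6.70 ± 0.231 and Epcam, an epithelial adhesion protein, by 3.68 ± 0.189. Altogether 5009 of 14352 genes changed between tumour-free tissue and controls, 2599 higher and 2410 lower, and 2877 changed at least 2-fold. Scaled by library size alone, the median of all genes was 0.425, against -0.00878 with TMM, and the split became 5706 higher and 1178 lower. That scaling left only 6 lower genes of oxidative phosphorylation, 22 lower and 2 higher of fatty acid oxidation, 9 and 1 of fatty acid synthesis and 7 and 1 of lipid droplets, and raised the higher genes of mitosis to 24.

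**Figure D2:**
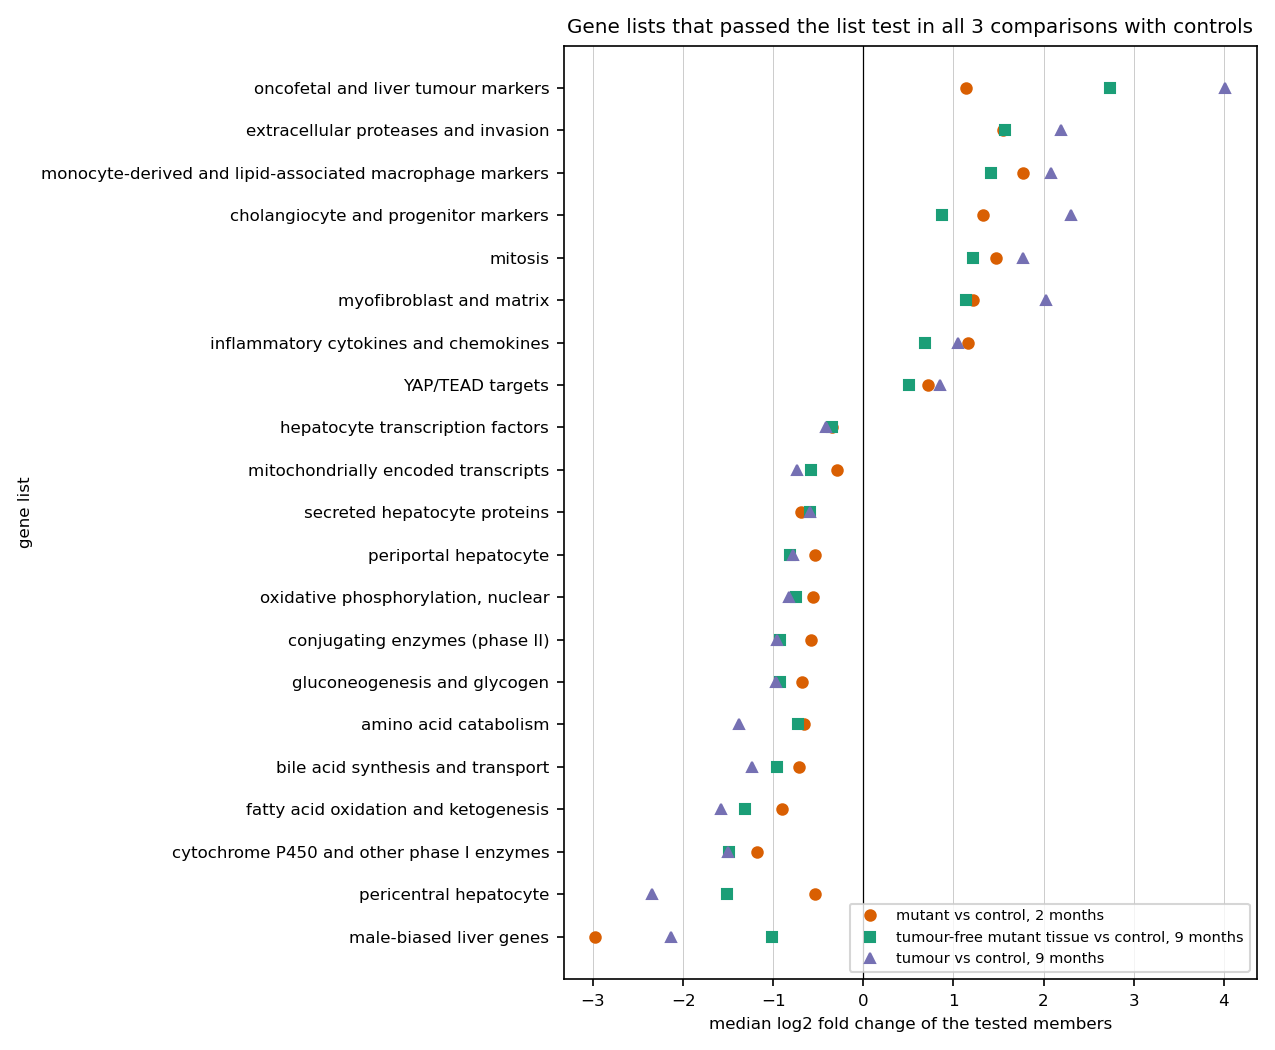
Median log2 fold change of the tested members of each of the 21 gene lists that passed the list test in mutants at 2 months, tumour-free tissue at 9 months and tumours at 9 months, each against controls of the same age, with 1 symbol per comparison. With TMM scaling 8 lists lay above 0 and 13 below 0 in all 3 comparisons, and scaled by library size alone the hepatocyte transcription factors turn positive at 9 months.

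Tumours against 9-month controls (n = 3 and 3) show what set the tumours apart from normal liver. Fosl2 rose from 13.9 ± 5.38 to 635 ± 71.9 CPM (log2 change 5.50 ± 0.363, adjusted p = 0.000417). Jun was at 493.1 ± 84.2 CPM in tumours (1.71 ± 1.03, adjusted p = 0.268), and without control 1 it passed (3.93, adjusted p = 0.00826, range over the alternatives 0.00826 to 0.506). Myc was at 26.6 ± 15.5 CPM in tumours and 9.81 ± 8.06 CPM in controls and did not pass (1.42 ± 0.675, adjusted p = 0.172). Without all 9-month libraries numbered 1, whose immediate early genes were high, it did pass (1.78, adjusted p = 0.047, range over the alternatives 0.0349 to 0.425). Endothelial transcripts of tumour vessels rose: of 9 markers of capillarised and tumour endothelium, 6 rose and none fell, or 8 when adjusted over the list alone (list adjusted p = 4.69e-05, adjusted p = 0.0988 with an estimated correlation). Esm1 went from 0.645 ± 0.33 to 44.1 ± 12.3 CPM, Apln, the ligand apelin, from 0.0952 ± 0.0867 to 12.4 ± 2.86 CPM, Angpt2, a regulator of vessel stability, from 0.966 ± 0.29 to 7.33 ± 3 CPM and Cd34 from 2.31 ± 0.803 to 36.7 ± 21.3 CPM. Of 39 genes of mitosis, 20 rose and none fell, or 29 when adjusted over the list alone (list adjusted p = 7.18e-10, adjusted p = 0.381 with an estimated correlation), with Hmmr at 3.13 ± 0.544 and Top2a at 2.43 ± 0.462.

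Genes of the pericentral zone and of Wnt signalling fell in tumours. Of 10 tested targets of Wnt and beta-catenin, 5 fell and none rose, or 8 when adjusted over the list alone (list adjusted p = 3.26e-05, adjusted p = 0.234 with an estimated correlation). Glul, glutamine synthetase, the mark of hepatocytes around the central vein, went from 980.7 ± 44.6 to 103.9 ± 72.8 CPM. The Wnt feedback genes Nkd1 and Rnf43 changed by -1.93 ± 0.283 and -1.26 ± 0.216, and the transcription factor Sp5 by -5.28 ± 0.522. Pericentral markers fell in 9 of 16 and rose in none, or fell in 10 when adjusted over the list alone (list adjusted p = 2.76e-06, adjusted p = 0.335 with an estimated correlation). Oat, ornithine aminotransferase, went from 1338 ± 170 to 33.6 ± 32.3 CPM and Rgn from 1848 ± 202 to 44.2 ± 42.1 CPM. Of 30 genes of amino acid catabolism 17 fell and none rose, or 21 fell and 2 rose when adjusted over the list alone (list adjusted p = 3.08e-08, adjusted p = 0.0988 with an estimated correlation), with Kmo at -2.08 ± 0.25 and Agxt at -2.73 ± 0.397. Of 9 genes of the urea cycle 6 fell and none rose, or 7 when adjusted over the list alone (list adjusted p = 0.000297, adjusted p = 0.27 with an estimated correlation). Otc, ornithine transcarbamylase, went from 627.5 ± 50.7 to 19.7 ± 12.8 CPM and Ass1, argininosuccinate synthase, from 1048 ± 90.4 to 351.1 ± 96.1 CPM. Fatty acid oxidation and ketogenesis fell in 27 of 33 genes and rose in 1, or 29 and 1 when adjusted over the list alone (list adjusted p = 1.33e-13, adjusted p = 0.0736 with an estimated correlation), with the carnitine carrier Slc25a20 at -1.97 ± 0.166 and Acaa1b at -5.22 ± 0.359.

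Matrix, oncofetal and amino acid stress genes rose in tumours. Of 23 matrix genes, 17 rose and none fell, or 18 when adjusted over the list alone (list adjusted p = 2.76e-06, adjusted p = 0.355 with an estimated correlation), with Sparc, a matrix glycoprotein, from 64.7 ± 16.7 to 314.4 ± 81.4 CPM and Fbn1 at 3.12 ± 0.403. Of 17 oncofetal and tumour markers, 11 rose and none fell, or 14 when adjusted over the list alone (list adjusted p = 5.16e-06, adjusted p = 0.0988 with an estimated correlation), with Igf2bp2 at 2.85 ± 0.308 and Tff3, a mucosal trefoil peptide, at 7.72 ± 1.11. Of 19 genes of the ATF4 response 11 rose and 1 fell, or 12 and 1 when adjusted over the list alone (list adjusted p = 0.000307, adjusted p = 0.171 with an estimated correlation), with Aldh18a1, of proline synthesis, at 3.90 ± 0.251 and Mthfd2, of mitochondrial folate metabolism, at 2.89 ± 0.281. Cyp2a4, a female-biased P450, rose from 49.4 ± 41.2 to 2384 ± 1030 CPM. Cyp4a14 changed by -10.45 ± 0.517 and Elovl3 by -9.10 ± 0.768, and Olig1 had no count in any tumour and was at least 363-fold lower. In all, 3593 of 14332 genes changed, 1971 higher and 1622 lower, and 2723 changed at least 2-fold. Scaled by library size alone, the median of all genes was 0.475, against 0.0149 with TMM. Then 5482 genes passed, 4664 higher and 818 lower, with 3 lower genes of the urea cycle and 13 lower and 2 higher of amino acid catabolism. The count depended on each control, at 1973 without control 1, 2188 without control 2 and 1419 without control 3, and 1 fit over all 5 groups gave 6612.

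**Figure D3:**
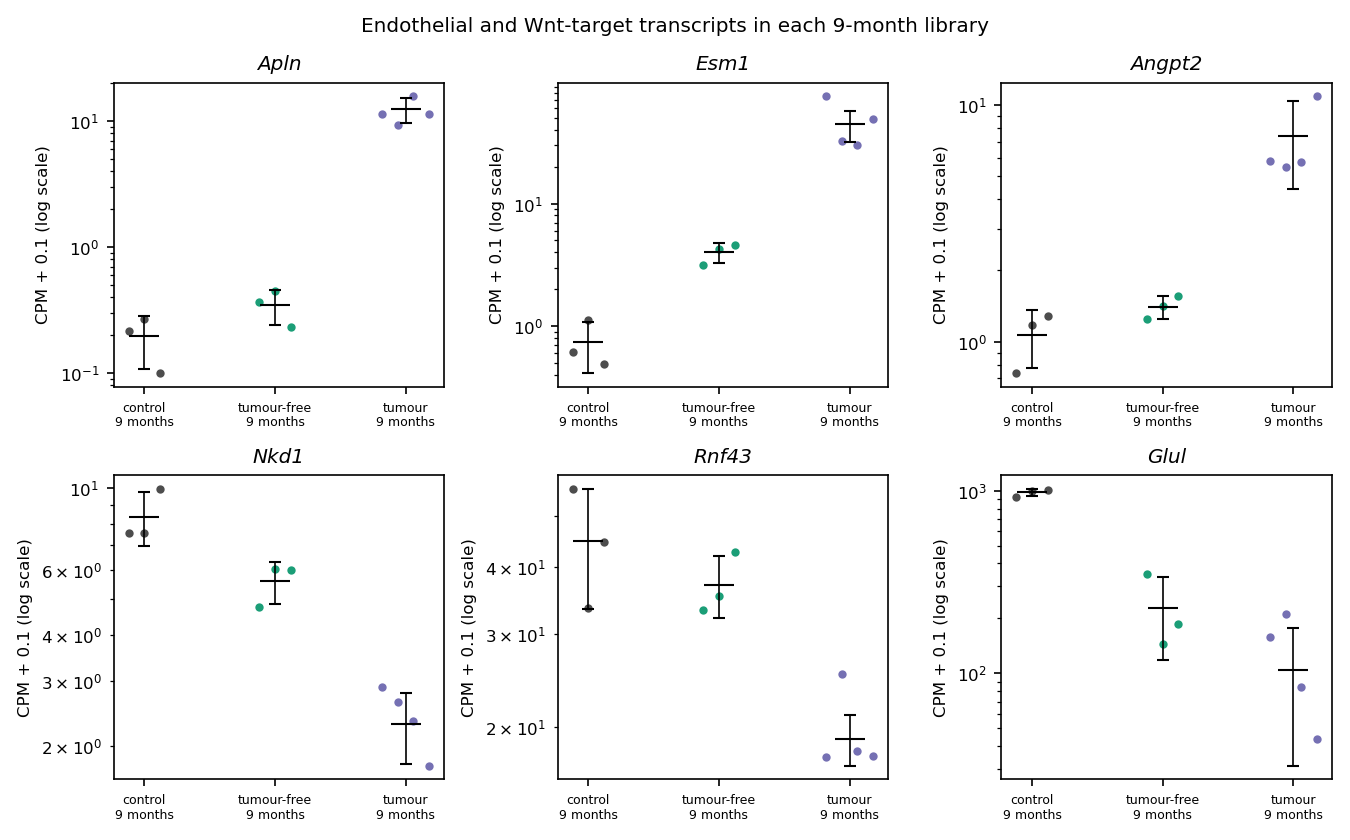
Level of 3 endothelial and 3 Wnt-target genes in each 9-month library, as CPM plus 0.1 on a log axis, with 1 point per library (tumours 1a and 1b separately) and black bars for the mean and SD over animals. Apln averaged 0.248 CPM in tumour-free tissue and 12.4 CPM in tumours.

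Tumours against tumour-free tissue of the same 3 animals address what the tumour adds to the mutant background. Both genes that changed were endothelial: Apln rose from 0.248 ± 0.109 to 12.4 ± 2.86 CPM (log2 change 5.59 ± 0.384, adjusted p = 0.0262) and Esm1 from 3.91 ± 0.732 to 44.1 ± 12.3 CPM (3.48 ± 0.278, adjusted p = 0.0364), among 14566 tested genes, of which 1454 had an unadjusted p under 0.05. Of 10 markers of capillarised and tumour endothelium these 2 rose, or 7 when adjusted over the list alone (list adjusted p = 8.51e-10, adjusted p = 0.128 with an estimated correlation), and the test of whether the list moves on balance one way, which does not compare it with other genes, gave adjusted p = 0.00672. Angpt2 (2.47 ± 0.35, adjusted p = 0.183) and Cd34 (7.54 ± 1.08 and 36.7 ± 21.3 CPM, adjusted p = 0.249) lay in the same direction. None of 10 Wnt and beta-catenin targets passed over all genes, and 6 fell when adjusted over the list alone (list adjusted p = 2.23e-08, adjusted p = 0.485 with an estimated correlation). Axin2, the classical Wnt target, was at 12.9 ± 0.362 CPM in tumour-free tissue and 3.06 ± 1.61 CPM in tumours (-2.06 ± 0.396, adjusted p = 0.224), and Rnf43 was at 37.0 ± 4.98 and 18.9 ± 2.08 CPM. None of 39 genes of mitosis passed by either adjustment, with a median of 0.587 (list adjusted p = 9.44e-14, adjusted p = 0.485 with an estimated correlation), as in Mki67, the proliferation antigen, at 5.66 ± 0.997 and 9.76 ± 1.77 CPM. Fosl2 (-0.47 ± 0.204, adjusted p = 0.517), Jun (-0.36 ± 0.279, adjusted p = 0.754) and Myc (0.56 ± 0.754, adjusted p = 0.876) did not pass. Each call needed all 3 tumour-free libraries: with any 1 of them left out no gene passed, Apln reached adjusted p = 0.186 to 0.39 and Esm1 0.39 to 0.524, and without tumour 1b Esm1 reached 0.136 and 1 gene passed. The count was 63 without both tumours of mutant 1, 30 without tumour 3, 435 with DESeq2, 0 with limma voom, and 380 in 1 fit over all 5 groups. With the animal as a block neither Apln (adjusted p = 0.0866) nor Esm1 (adjusted p = 0.255) passed, and 1 other gene did.

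Controls at 9 months against controls at 2 months (n = 3 and 6) describe age together with the sequencing run. A difference in inherited background may add to both, as the 9-month controls carried transcripts of chromosome 17 that the younger ones lacked, given under the other observations. Lipid droplet genes rose in 9 of 11 and fell in none, or rose in 10 when adjusted over the list alone (list adjusted p = 1.69e-09, adjusted p = 0.157 with an estimated correlation). Cidec, which fuses droplets, went from 1.58 ± 0.478 to 92.7 ± 51.5 CPM, Mogat1, an acyltransferase of triglyceride synthesis, from 0.56 ± 0.203 to 19.6 ± 11.9 CPM, and Fitm1 from 25.4 ± 5.4 to 170.5 ± 58.6 CPM. Cidea had 3 counts over the 6 younger controls and 63.6 ± 49.5 CPM in the older ones, a ratio of 1750 with a 95% counting interval of 598 to 8480. Of 22 genes of fatty acid and triglyceride synthesis, 13 rose and none fell, or 19 rose and 1 fell when adjusted over the list alone (list adjusted p = 1.43e-08, adjusted p = 0.161 with an estimated correlation), with Gpam at 1.09 ± 0.158 and Me1 at 1.28 ± 0.137. Of 18 female-biased genes 9 rose and none fell, or 10 when adjusted over the list alone (list adjusted p = 8.88e-08, adjusted p = 0.202 with an estimated correlation), with Cyp2b9, a P450, from 0.372 ± 0.415 to 135.9 ± 78.6 CPM and Hao2 at 6.04 ± 0.48. Of 20 male-biased genes 7 fell and 3 rose, or 12 and 3 when adjusted over the list alone (list adjusted p = 0.000831, adjusted p = 0.835 with an estimated correlation): Cyp4a12b changed by -3.33 ± 0.485 and Cyp4a12a by 1.62 ± 0.185. Here the 2-month controls differed. Against only controls 1 to 3 of them, 3 fell and 2 rose, or 9 and 2 when adjusted over the list alone (list adjusted p = 0.0302, adjusted p = 0.875 with an estimated correlation). Against only controls 4 to 6, 13 fell and 3 rose, or 15 and 3 when adjusted over the list alone (list adjusted p = 1.1e-06, adjusted p = 0.495 with an estimated correlation). Kupffer cell and macrophage markers fell in 5 of 14 and rose in none, or fell in 9 when adjusted over the list alone (list adjusted p = 7.83e-05, adjusted p = 0.835 with an estimated correlation), with Vsig4, a complement receptor of Kupffer cells, at -1.27 ± 0.202. Cdh1, E-cadherin, went from 60.0 ± 16.6 to 5.41 ± 0.671 CPM. Fosl2 (0.14 ± 0.267, adjusted p = 0.767) and Myc (0.36 ± 0.511, adjusted p = 0.693) did not pass. The direction of Fosl2 rested on 9-month control 1 at 19.9 CPM, with controls 2 and 3 at 12.5 and 9.36 CPM and the 2-month controls at 12.5 ± 3.7 CPM. Jun (3.12 ± 0.798) passed at adjusted p = 0.0431, and leaving out any of 2-month controls 1 to 6 or 9-month control 1 ended that call (adjusted p = 0.0731 to 0.106), with a log2 change of 0.87 without 9-month control 1. Altogether 1616 of 13545 genes changed, 988 higher and 628 lower, 581 of them at least 2-fold, and 797 changed without 9-month control 2 and 925 without 9-month control 3. The count was 564 against only 2-month controls 1 to 3, 1090 against only 4 to 6, 1056 in 1 fit over all 5 groups and 384 with the replicate number as a block.

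**Figure D4:**
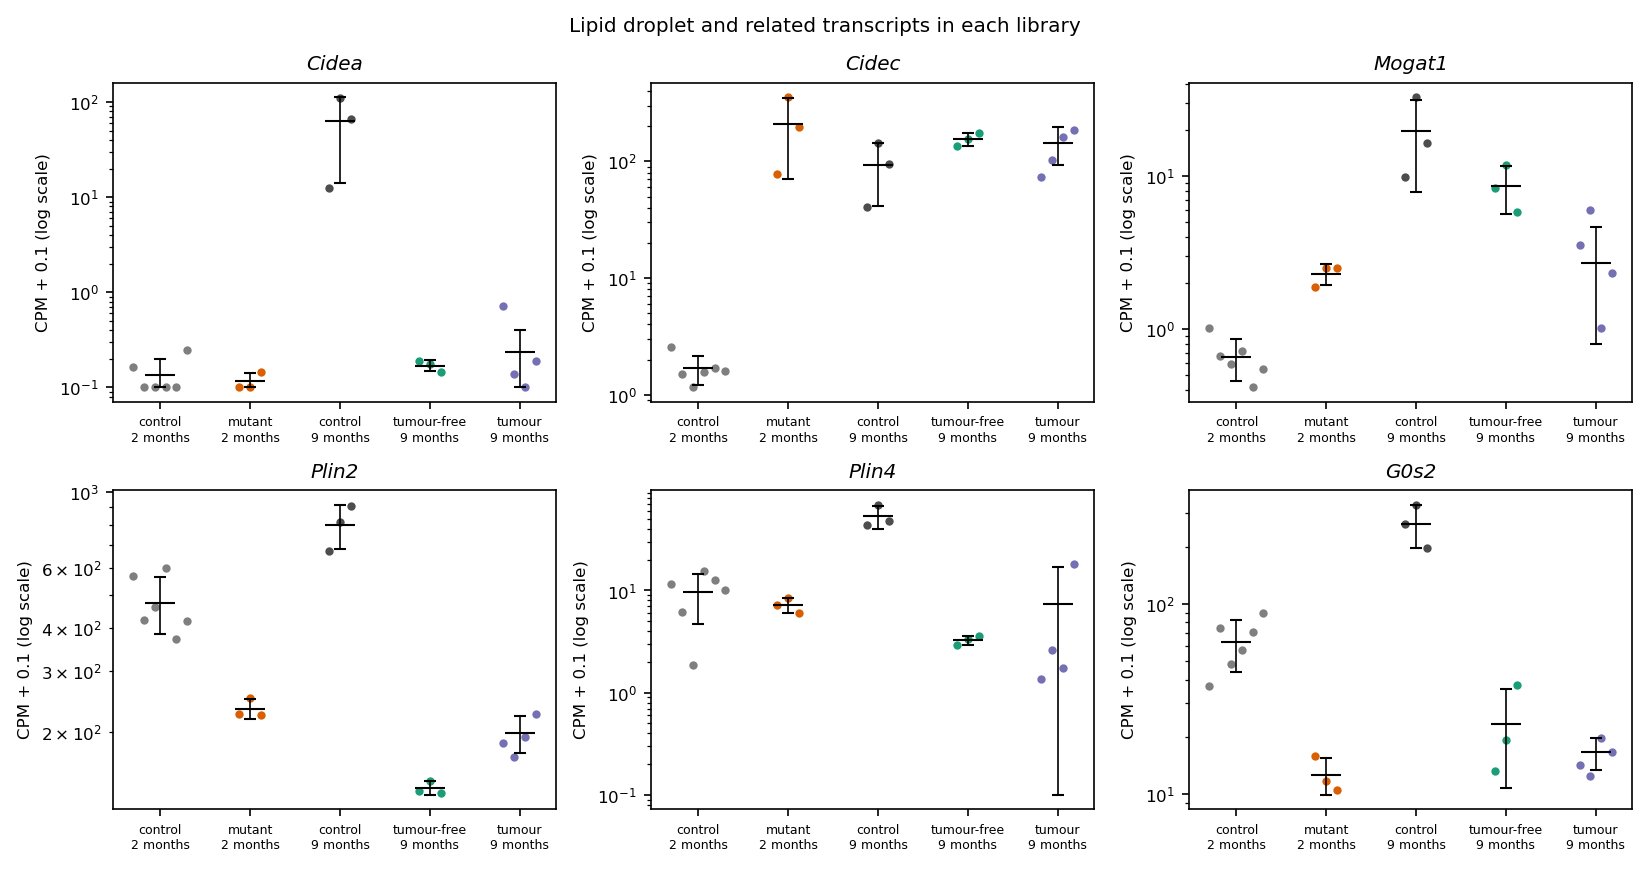
Level of 6 genes of the lipid droplet list in each library, as CPM plus 0.1 on a log axis, in all 5 groups, with 1 point per library and black bars for the mean and SD over animals. Plin2 averaged 473.7 CPM in 2-month controls, 799.3 CPM in 9-month controls and 136.8 CPM in 9-month tumour-free tissue.

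Whether the mutant's difference from controls changed between the times was tested as the 9-month contrast of tumour-free tissue minus the 2-month contrast, in which a shift common to a run cancels. Of 14707 genes, 223 differed, 68 with a higher and 155 with a lower contrast at 9 months, and 179 differed at least 2-fold. Lipid droplet genes had a lower contrast at 9 months in 5 of 11 and a higher one in none, or lower in 6 when adjusted over the list alone (list adjusted p = 1.62e-12, adjusted p = 0.0118 with an estimated correlation). Cidec was far higher in 2-month mutants (210.5 ± 140 CPM) than in their controls (1.58 ± 0.478 CPM), while both 9-month groups carried it (156.1 ± 20 and 92.7 ± 51.5 CPM), a difference of -6.29 ± 0.687. Plin2 (-1.53 ± 0.225), Plin4 (-3.65 ± 0.645) and Mogat1 (-3.14 ± 0.545) differed the same way. Of 33 genes of fatty acid oxidation 5 had a lower contrast and none a higher one, or 6 when adjusted over the list alone (list adjusted p = 2.54e-08, adjusted p = 0.429 with an estimated correlation), with the thioesterases Acot2 (-2.07 ± 0.349) and Acot4 (-1.97 ± 0.323) among them. Cdh1 differed by 3.26 ± 0.374 and Afp, the fetal albumin, by 4.80 ± 0.842, with 10.2 ± 8.4 CPM of Afp in 9-month tumour-free tissue and at most 1.27 ± 0.614 CPM in the other 3 groups. Fosl2 (0.01 ± 0.357, adjusted p = 1), Jun (-3.10 ± 1.01, adjusted p = 0.18) and Myc (0.54 ± 0.944, adjusted p = 0.895) did not pass. Scaled by library size alone, the median of all genes was 0.121, against -0.0294 with TMM. The split became 92 higher and 87 lower of 179 genes, with 3 lower of fatty acid oxidation. The count was 110 without 2-month mutant 2, 148 without 2-month mutant 1, 115 without tumour-free sample 2 and 118 without tumour-free sample 3. With the replicate number as a block it was 54, and Cidec, Mogat1 and Afp did not pass (adjusted p = 0.0594, 0.0594 and 0.129, at most 0.225 over the alternatives). Mogat1 and Afp did not pass with limma voom or with 1 fit over all 5 groups either, nor Plin4 with the latter.

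The same test with tumours in place of tumour-free tissue gave 385 of 14701 genes, 131 with a higher and 254 with a lower contrast at 9 months, 307 of them at least 2-fold. Of 9 markers of capillarised and tumour endothelium 2 had a higher contrast, or 6 when adjusted over the list alone (list adjusted p = 9.19e-09, adjusted p = 0.0476 with an estimated correlation): Esm1 differed by 5.43 ± 0.477, with 1.00 ± 0.418 CPM in 2-month mutants, and Angpt2 by 3.31 ± 0.595. Of 16 pericentral genes 5 had a lower and 1 a higher contrast, or 14 and 1 when adjusted over the list alone (list adjusted p = 1.28e-10, adjusted p = 0.165 with an estimated correlation). The higher one was Cyp2a5 (8.46 ± 0.835), and Aldh3a2 differed by -1.85 ± 0.24. At 2 months Cyp2a5 was at 391.4 ± 205 CPM in controls and 1.46 ± 0.211 CPM in mutants. At 9 months it was at 1010 ± 117 CPM in controls and 1343 ± 1020 CPM in tumours, and did not pass between these (0.38 ± 0.508, adjusted p = 0.613). Cyp2a5 also passed in the change with time of tumour-free tissue (5.81 ± 1.09, adjusted p = 0.0189), a value not followed over the alternatives. Lipid droplet genes had a lower contrast in 4 of 11, by either adjustment (list adjusted p = 1.1e-09, adjusted p = 0.0409 with an estimated correlation), with Cidec at -6.40 ± 0.722 and Mogat1 at -4.81 ± 0.709. Of 33 genes of fatty acid oxidation 8 had a lower contrast and none a higher one, or 14 and 1 when adjusted over the list alone (list adjusted p = 1.28e-10, adjusted p = 0.0538 with an estimated correlation). Fosl2 (-0.45 ± 0.37, adjusted p = 0.597), Jun (-3.45 ± 0.972, adjusted p = 0.0824) and Myc (1.11 ± 0.809, adjusted p = 0.539) did not pass, and Jun passed without 9-month control 3 (adjusted p = 0.0338, range over the alternatives 0.0134 to 0.472). Scaled by library size alone, the median of all genes was 0.183, against 0.0277 with TMM. The split became 173 higher and 156 lower, with 2 lower lipid droplet genes and 5 of fatty acid oxidation. The count was 136 without 2-month mutant 1, 131 without 2-month mutant 2, 248, 246 and 173 without 9-month controls 1, 2 and 3, 819 without both tumours of mutant 1 and 718 without tumour 3. With the replicate number as a block it was 4, and Esm1, Angpt2, Aldh3a2, Cidec and Mogat1 did not pass (adjusted p from 0.0621 to 0.199, the highest of each gene's alternatives), while Cyp2a5 did.

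Many of the changed genes were shared between the comparisons. Of 13556 genes tested in both, 1851 were higher and 1769 lower in mutants at 2 months and in tumour-free tissue at 9 months, where independent lists would share 533 and 479, and 18 went opposite ways. These groups have no library in common, and Fabp1, Slco1a1, Tcam1 and St14 are examples from either direction. Mutants at 2 months and tumours shared 1377 higher and 1213 lower genes of 13523, against 400 and 323 for independent lists, and 20 went opposite ways. Tumour-free tissue and tumours shared 1566 higher and 1395 lower genes of 14066 and none went opposite ways. Those comparisons use the same 3 controls and the same 3 mutants. Unchanged groups simulated with shared controls, but without shared mutants, gave at most 1 shared gene per direction in 20 draws. Such groups had hardly any calls to share, so these draws cannot show how many shared genes the common controls add. Shared controls alone gave a mean correlation of the log2 changes across genes of r = 0.516, against 0.912 in the data. The covariance of the log2 changes, which also counts their size, averaged 0.0869 in the draws, against 1.79 in the data.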

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

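The tests of single libraries and of change with time reported here were planned, and the splits of the samples too.

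Single libraries stood far from their group, by Dixon's test, in 11 of 55 values among the 6 controls at 2 months and in 4 of 40 among the 4 tumours, where chance gives about 1 in 20 groups. These tallies are a rough guide only. Tumours 1a and 1b come from 1 mouse, Alb enters as share and as CPM, and values under the floor are included. In 2-month control 2 Alb was at 86210 CPM, or 7.58% of counts, with the other controls at 102600 to 106300 CPM, or 8.85 to 9.43%. The same library was highest for Cyp4v3 at 530.3 CPM (others at most 423.1), Lgals3 at 10.8 CPM (at most 6.95), Ly6d at 3.52 CPM (at most 1.96) and Vil1 at 0.564 CPM (at most 0.395). In 2-month control 1 Cidec was at 2.49 CPM (others at most 1.58) and Sult1e1 at 0.524 CPM (at most 0.211), and in 2-month control 3 Gpam was at 348.9 CPM (at most 261.4). In 2-month control 6 Slc15a1 was at 0.150 CPM and in 2-month control 5 Krt20 at 0.0790 CPM, each with no count in the others. With no count elsewhere the test had to call them, and both lie under the floor of 3 counts (0.225 and 0.237 CPM). Tumour 1b was highest for Ass1 at 614.8 CPM (others at most 309.1), Rnf43 at 25.1 CPM (at most 17.9) and Sp5 at 0.159 CPM (at most 0.0439), and tumour 3 for Angpt2 at 10.8 CPM (at most 5.71). No explanation was tested for these libraries.

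The mutant's difference from controls changed with time for 223 genes in tumour-free tissue. The median over the lipid droplet list moved by -1.53 on the log2 scale (adjusted p = 0.0118 with an estimated correlation). Among named genes Cidec (-6.29), Plin4 (-3.65), Mogat1 (-3.14), Acot2 (-2.07), Acot4 (-1.97) and Plin2 (-1.53) had a lower contrast at 9 months, and Afp (4.80) and Cdh1 (3.26) a higher one. In tumours 385 genes changed in this way. The lipid droplet median was -1.39 (adjusted p = 0.0409 with an estimated correlation) and that of the tumour endothelium list 1.13 (adjusted p = 0.0476 with an estimated correlation). Cidec (-6.40), Mogat1 (-4.81) and Aldh3a2 (-1.85) had a lower contrast, and Cyp2a5 (8.46), Esm1 (5.43) and Angpt2 (3.31) a higher one. Cyp2a5 had a higher contrast in tumour-free tissue as well (5.81). Time goes with the sequencing run and with the animals' age, and a run effect that differs between mutants and controls cannot be told apart from either. A difference in inherited background between the animals, left open under the other observations, may enter as well. No biological explanation was tested.

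Splits of the samples into groups of the same sizes, the real split included, gave as many genes in 1 of 84 at 2 months (5883, highest other 19) and in 1 of 84 between the controls (1616, highest other 42). This is the smallest share that 84 splits can give. It argues against chance as the source of these counts without excluding it. For tumour-free tissue, tumours, and tumours against tumour-free tissue, the 10 splits are too few for a share under 0.05 (1 of 10 each: 5009 with highest other 2, 3593 with highest other 1, and 2 with highest other 0). For the changes with time, 3 of 100 splits gave as many as 223 genes (highest other 4819) and 4 of 100 as many as 385 (highest other 4775). These splits also undo the difference between mutants and controls at each time, which the change with time takes as given, so the share says nothing about chance for these counts. The highest other split exchanges mutants and controls at 9 months and calls many times the real count, which is a structure of the samples.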

How the results depend on the processing

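Leaving out all 9-month libraries numbered 1, the subsets of the 2-month controls (gene and list tests), and list tests without 9-month control 1 were chosen after seeing the data. So was the list test with the animal as a block for tumours against tumour-free tissue, which passed 23 lists, as many as without the block. The other alternatives were planned.

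The counts of changed genes kept within 1.5 times with RLE size factors and with protein coding genes only in all 7 comparisons. A 2-fold minimum left 2352 genes at 2 months, 2877 in tumour-free tissue and 581 between the controls, since it asks for more. It left 976 higher and 733 lower genes shared by 2-month mutants and tumour-free tissue, 829 and 547 shared by 2-month mutants and tumours, and 830 lower genes shared by tumour-free tissue and tumours. For the values that follow the cause was not tested. DESeq2 gave 435 genes for tumours against tumour-free tissue, 524 for the change with time in tumour-free tissue and 861 for that in tumours. Limma voom gave 0 for tumours against tumour-free tissue, where edgeR had 1454 genes at an unadjusted p under 0.05, and no filter gave 47. Library size alone gave 5482 for tumours against controls. The fit over all 5 groups gave 6612 for tumours against controls, 380 for tumours against tumour-free tissue, 1056 between the controls and 54 for the change with time in tumour-free tissue. The replicate block gave 3290 at 2 months, 1 for tumours against tumour-free tissue (paired by animal), 384 between the controls, and 54 and 4 for the changes with time in tumour-free tissue and tumours.

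Leaving out 1 library in turn gave 1419 to 3825 genes for tumours against controls, 0 to 63 for tumours against tumour-free tissue, 797 to 1899 between the controls, 110 to 293 for the change with time in tumour-free tissue and 131 to 819 for that in tumours. At 2 months it gave 4324 to 5832 genes and in tumour-free tissue 3351 to 4870, both within 1.5 times. Without all 9-month libraries numbered 1, tumours against controls gave 1743 and the change with time in tumours 659. With 2-month controls 1 to 3 only, the controls differed in 564 genes. The list test with an estimated correlation passed 0 lists in each of the first 5 comparisons, 1 for the change with time in tumour-free tissue and 2 for that in tumours, against 28, 30, 31, 23, 17, 11 and 22 with the preset correlation. Fry passed 1 list for tumours against tumour-free tissue, 7 between the controls, 4 and 12 for the changes with time, and without 9-month control 1 the preset test passed 7 for the change in tumour-free tissue. No call of a named gene or list reversed under any alternative run.

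Among 167 results for named genes the replicate block ended 12 calls, the most of any single alternative: 2 of 2 for tumours against tumour-free tissue, 2 of 13 between the controls, and 3 of 8 and 5 of 6 for the changes with time in tumour-free tissue and tumours. Limma voom and the fit over all 5 groups ended 5 each, the 2-fold minimum 4 and no filter 3, and DESeq2, RLE size factors, library size alone and protein coding genes only ended none. Leaving out 1 library in turn ended 14 of 1473. The cause was not tested.

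On simulated 2-fold changes the test found 53.7% of genes at 2 months, 37.3% in tumour-free tissue and 1.49% in tumours against controls. Of simulated 4-fold changes it found 9 of 12 genes under 5 CPM and 54 of 54 others at 2 months, 8 of 14 and 50 of 52 in tumour-free tissue, and 1 of 16 and 32 of 50 in tumours against controls. Each simulation changed 200 genes. Far more passed in these real comparisons, which makes the adjusted threshold less strict there, so these rates may be too low for them. Depth alone was not varied, so its part in this limit is not known.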

Other observations

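All tests of the 3 patterns weighed here were chosen after the result was seen, except the test of clustering in the genome, and the genes of the next paragraph and of the last were chosen after their values were seen.

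Some genes known from gut epithelium rose in mutants and others fell, and no list of such genes was tested. Muc13, a mucin, rose from 0.0718 ± 0.0633 to 41.9 ± 24.4 CPM at 2 months (log2 change 9.02 ± 0.498) and was at 226.6 ± 63.5 CPM in tumour-free tissue and 146.5 ± 137 CPM in tumours. Vil1 rose too, by 7.51 ± 0.315 at 2 months and by 7.77 ± 0.291 in tumour-free tissue. Slc15a1 rose at both times, to 14.1 ± 8.68 and 8.24 ± 3.49 CPM from 0.02503 ± 0.0613 and 0.0188 ± 0.0326 CPM, as did Krt20, to 9.66 ± 6.74 and 6.14 ± 2.44 CPM from 0.0132 ± 0.0323 and 0.0952 ± 0.0867 CPM. Mep1a rose to 2.15 ± 1.31 CPM at 2 months, with no count in the controls, and to 67.4 ± 23.6 CPM from 0.133 ± 0.142 CPM in tumour-free tissue. It did not pass in tumours (adjusted p = 0.0576), but did without both tumours of mutant 1 (adjusted p = 0.0403, range over the alternatives 0.00959 to 0.26), at 73.2 and 85.2 CPM in tumours 1a and 1b and 1.11 and 1.36 CPM in tumours 2 and 3. Tff1 rose in tumour-free tissue, from 0.0575 ± 0.0579 to 8.25 ± 7.29 CPM. Ly6d, a surface protein of epithelia and lymphoid cells, rose by 7.69 ± 0.401 at 2 months and by 5.32 ± 1.05 in tumour-free tissue. Fabp2, the intestinal fatty acid binding protein, fell from 91.1 ± 17.6 to 25.1 ± 8.78 CPM at 2 months and from 185.9 ± 46.1 to 19.9 ± 6.05 CPM in tumour-free tissue and 16.3 ± 5.54 CPM in tumours. Lgals4, a lectin of gut epithelium, changed by -2.09 ± 0.295 at 2 months, -2.61 ± 0.23 in tumour-free tissue and -2.77 ± 0.241 in tumours. Egfr, the receptor of epidermal growth factor, fell from 717.4 ± 172 to 149.2 ± 34.2 CPM at 2 months and from 134.0 ± 56.3 to 43.2 ± 10.6 CPM in tumour-free tissue.

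Single libraries also stood apart from their group in other genes. Tumour 3 carried 2272 CPM of Gclc, of glutathione synthesis, against 355.6 to 419 CPM in the other tumours, and 330.2 CPM of Nqo1 and 324.7 CPM of Slc7a11, both of the antioxidant response. Tumours 1a and 1b carried 24.6 and 36.0 CPM of Dlk1, a fetal liver gene, and tumours 2 and 3 carried 0 and 0.132 CPM. Tumour-free sample 2 carried 7.28 CPM of Sftpc and 5.27 CPM of Scgb1a1, transcripts of lung epithelium, where Sftpc had no count in the other 18 libraries.

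In the 9-month animals numbered 1, immediate early and heat shock transcripts were high. Of 25 members of these lists, 23 were highest in number 1 in each of the 3 groups, and 0 were highest in number 1 in both 2-month groups. Any other choice of 1 animal per group had at most 1, but the 23 leave few genes for other choices, so this is no separate test. The tumour-free tissue and the tumours numbered 1 also come from the same mouse. Transgene expression in control 1 is argued against by its Fosl2 level of 19.9 CPM, near the 8.38 to 19.2 CPM of the other controls, and a difference in depth by its 20.9 M counts. Conditions shared by these animals at collection may explain the pattern, and a biological difference between the animals remains open and untested.

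Some genes were on in part of the 9-month animals and off in the rest, 37 of 14829. Only 45.5% of 22 genes that varied among the mutants agreed between the tumour and the tumour-free tissue of each animal. The 37 genes did not cluster in the genome beyond random lists (permutation p = 0.23). The genes that disagreed argue against a genetic difference between the mice as the cause of the whole set. The share random patterns would give was not worked out, so the 45.5% says nothing for or against such a difference in part of the set. Scattered differences would not cluster, so the clustering test cannot decide this. For single genes a genetic difference remains open. Ifi44l (chromosome 3) and Myom2 (chromosome 8), picked after their values were seen, were on in 9-month controls 1 and 2 and in both tissues of mutants 1 and 3. Neither had a count in 9-month control 3, 9-month mutant 2 or the 2-month animals. For 3 of the 37, Gm10503, H2-Ea-ps and Gm8810, the 9-month controls and mutant 1 carried the transcript and the other mice did not. They lie within 5.15 Mb of chromosome 17 (30920338 to 36067753, permutation p = 0.0001, the smallest they can give), so an inherited segment may differ between the mice. Such a segment would also enter the comparisons with the 9-month controls. Gm10260, on chromosome 13, followed the same animals, at 16.6 to 27.3 CPM against at most 0.269 CPM in the others. That is over the limit of 0.1 CPM for a gene that is off, so the test of the span left it out. The segment alone may then not account for every transcript with this pattern, but reads that Gm10260 may share with other genes were not examined. Of the 9 samples at 9 months, 4 lack the 3 transcripts, and a difference between the runs alone would not part samples of 1 run. But the 3 were picked for being absent in both tissues of mutants 2 and 3, so this is no separate test.

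Among the 2-month controls, numbers 1 to 3 differed from 4 to 6 in 62 of 12998 genes, 29 higher and 33 lower. Of the 33, 14 were genes or pseudogenes of the major urinary proteins, with Mup7 at 1.38 to 7.83 CPM in 1 to 3 and 1355 to 1811 CPM in 4 to 6; reads shared between these paralogs were not examined. Cish (log2 difference -2.77 ± 0.187) and Onecut1 (-2.91 ± 0.196) were lower too, and Bcl6 (2.44 ± 0.225), Cyp2b10 (2.73 ± 0.258) and Cd36 (2.07 ± 0.159) were higher, with adjusted p of at most 0.00708. The 10 splits are too few for a share under 0.05 (1 of 10, highest other 2). The male-biased list was lower in 1 to 3 (adjusted p = 0.00071), with 2 of 20 members lower and none higher, but with an estimated correlation adjusted p was 0.853. The urinary protein genes, Cish, Onecut1 and Bcl6 differ the way weaker growth hormone signalling in 1 to 3 would move them, but the explanation was found from them and they do not test it, so a difference in growth hormone dependent transcription remains open. Handling or litter was not tested, as the labels give neither.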
